A study of Mus musculus with 12 samples.

How the data were processed

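RNA-seq counts were taken as deposited. Per the labels' protocols, colons were flushed and opened, the distal part was processed separately, epithelium was shaken off in EDTA and crypts were frozen. Poly(A)+ RNA entered a TruSeq RNA v2 library, a kit that does not mark strand. Per the submitters' processing notes, the authors used Trimmomatic 0.39, TopHat2 2.0.6 and HTSeq, whose version is not given in the sources used here, with build mm9. The annotation, the counting options and any filter are not given in the sources used here. The authors deposited 1 table of whole-number read counts for 23365 gene symbols and 12 libraries, with no line for unassigned reads. Reads from overlapping or antisense genes cannot be told apart.

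Libraries were grouped by their labels into CNV, CNV_DSS, GF and GF_DSS, with 3 in each. No library pair within a group agreed within sampling noise, since the chi-square per gene was at least 20.7. The labels do not state that the libraries come from separate animals, so p-values measure only the spread between these samples. Total counts ranged from 17481693 to 59308664. The floor of 3 counts over a group was 0.0356 CPM in CNV, 0.0246 in CNV_DSS, 0.053 in GF and 0.0174 in GF_DSS. List medians with genes at 0 counts set to their bound leave out genes at 0 in both groups compared. They can therefore rest on fewer members. Counting intervals at the 95% level and floors cover counting error only. Resampling intervals at that level cover the spread between genes and not that between libraries.

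Counts were fitted with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood method with TMM factors and filterByExpr, using all 12 libraries in 4 groups. This left 15017 genes. Contrasts were DSS in CNV, DSS in GF, GF against CNV without DSS, GF against CNV under DSS, and the difference of the DSS changes. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived from the quasi-likelihood F statistic.

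The contrasts, the tests of genes and of lists and the 37 lists, of which 23 are gene lists and 14 cell type lists, were chosen before the data were examined. So were the alternatives, apart from thinning, but not all tests of technical explanations. The lists cover antimicrobial defence, oxidases, interferon-stimulated genes, MHC class II, cytokines, goblet cells, stem cells, cell cycle, absorptive cells, regenerative epithelium, YAP targets, unfolded protein response, cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation, xenobiotic metabolism, bile acid and steroid handling, DNA methylation, circadian clock, tight junctions, NF-kB, hypoxia and immediate-early genes, and markers of immune, stromal and other epithelial cells. Of the 37, 36 had at least 5 tested members and were tested by camera in limma 3.58.1 with a correlation of 0.01, adjusted over lists within a contrast. Camera with an estimated correlation and fry were alternatives.

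Named genes were those with an adjusted p under 0.05, a mean of at least 5 CPM over all libraries, a symbol that is not a clone or predicted-gene name, and groups that do not overlap, which chance gives for 10% of genes. From these the 10 largest rises and 10 largest falls were taken, or 6 and 6 for the difference of DSS changes, without the overlap criterion. In addition, up to 4 members per list with the smallest adjusted p and 24 genes chosen in advance were added. Some genes that met this rule are not reported here.

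The procedure was tested on simulated counts for 14754 genes. For DSS in CNV it recovered 70% of 2-fold and 92% of 4-fold changes, for GF against CNV under DSS 66% and 92%, and for the difference of DSS changes 38% and 81%. The changes were set in CNV_DSS only, in 100 genes at each fold, so these percentages rest on the same genes. They are far fewer than the genes called in the data. No change was set for DSS in GF or for GF against CNV without DSS, so recovery there is not known. Alternatives were DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, limma-voom, other filters, fits of only the groups compared and leaving out each library. Thinning to 17481693 counts per library was chosen after seeing the data.

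Biotypes, gene order and sequence shared between genes came from GENCODE M21 on GRCm38. That is another build than mm9, so no coordinates are given. Of the tested genes, 14886 matched by symbol (99.1%). Shared sequence was the percentage of a gene's 50-base sequences found in another gene. Libraries were also regrouped, in 10 ways for each pair of groups and in 100 seeded draws from 200 ways for the difference of DSS changes. A first run of the last test drew 60, and these are the first 60 of the 100.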

Results

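Poly(A)+ RNA from crypts of the mouse distal colon was sequenced in 12 libraries, 3 in each of 4 groups. The groups were untreated control mice (CNV), mice with inflammation (CNV_DSS), germ-free mice (GF), which carry no microbes, and germ-free mice with inflammation (GF_DSS). DSS is dextran sulfate sodium, a polymer that injures the colon lining. Total counts per library were 24144124 to 33858921 in CNV, 37011123 to 45460072 in CNV_DSS, 17481693 to 21880551 in GF and 47423384 to 59308664 in GF_DSS. Of 23365 gene symbols, 15017 had enough counts to test. Unless another unit is given, gene values are log2 fold changes ± SE from edgeR with Benjamini-Hochberg adjustment (n = 3 libraries per group), and medians of lists are on the same scale.

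The first principal component held 53.6% of the variance and set CNV_DSS apart from the other groups. CNV_DSS replicate 17 lay at 136.7 on it, against 90.2 and 88.5 for replicates 16 and 18. The second component, with 22% of the variance, separated CNV (-74.7 to -63.7) from all other groups. CNV_DSS lay at 1.99 to 20.9 on it and the germ-free libraries at 25.2 to 41.0. All 12 libraries had Xist at or below 0.629 CPM (counts scaled to library size) and expressed the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y.

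**Figure D1:**
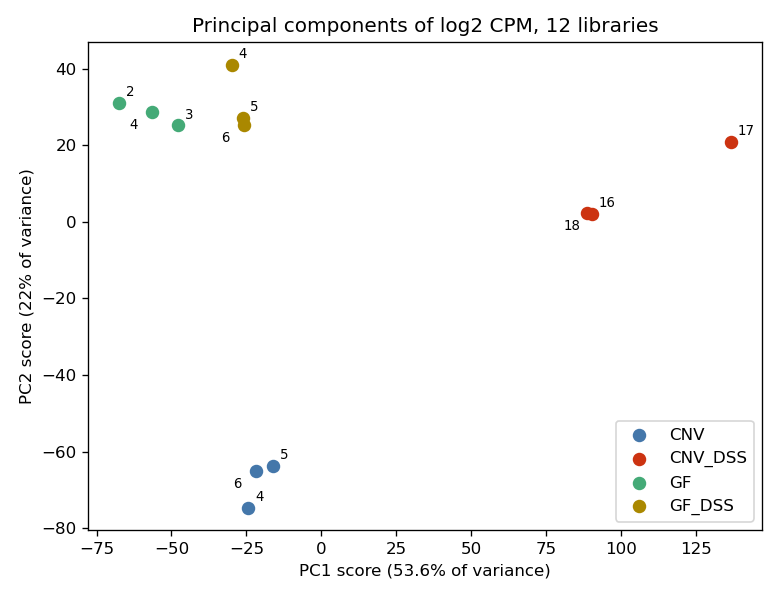
Scores of the 12 libraries on principal components 1 and 2 of log2 CPM, 1 point per library, coloured by group and labelled with the replicate number. The CNV_DSS libraries lie between 88.5 and 136.7 on component 1, and all other libraries below 0.

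The first question was how DSS changed the epithelial preparation of mice with a microbiota. S100a8, a calcium-binding protein of neutrophils, rose by 12.09 ± 1.29, adjusted p = 0.000196, and the inflammatory cytokine Il1b by 11.77 ± 1.08, adjusted p = 4.98e-05. The antimicrobial lectins Reg3b and Reg3g rose by 8.15 ± 1.76 and 7.26 ± 1.16, and the siderophore-binding protein Lcn2 by 8.70 ± 0.996. Reg3g went from 3.15 ± 1.5 CPM in CNV to 475 ± 636 CPM in CNV_DSS (SD, n = 3), so its level varied widely between the CNV_DSS libraries. The pentraxin Mptx1 went from 6930 ± 1107 to 4.44 ± 3.27 CPM (SD, n = 3).

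On the log2 scale Mptx1 fell by 10.59 ± 0.679 (adjusted p = 5.18e-06) and its relative Mptx2 fell by 9.34 ± 0.621. Mptx1 and Mptx2 share 17.9% and 18% of their 50-base sequences with another gene, so reads between them are uncertain. Other large falls were the manganese transporter Slc30a10 (-6.27 ± 0.243), the antimicrobial ribonuclease Ang4 (-5.004 ± 0.868), Pla2g4c (-6.01 ± 0.426), Slc37a2 (-5.45 ± 0.604), Tppp3 (-4.98 ± 0.404), Cpm (-4.23 ± 0.4) and Odf3b (-4.12 ± 0.347). Several of the largest rises started from 0 counts in CNV, and their size is a bound against 3 counts over the group. Irg1, the enzyme that makes itaconate, was at least 4150-fold higher and the prostaglandin synthase Ptgs2 at least 3500-fold higher. Clec4e, Osm, Trem1 and Cxcl3 were at least 1180-fold, 733-fold, 594-fold and 583-fold higher. S100a9 had 3 counts in CNV and a ratio of 8480 (95% counting interval 2900 to 41100). Retnlg had 1 count and a ratio of 5330 (957 to 211000), and Ccl3 had 2 counts and a ratio of 940 (260 to 7760).

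Of 40 interferon-stimulated genes, 34 rose and 0 fell (35 and 0 adjusted over the list alone, median 2.22), among them Igtp (4.37 ± 0.678) and Iigp1 (7.17 ± 1.18). Interferon-stimulated genes had a camera adjusted p = 1.41e-08 and adjusted p = 0.455 with an estimated correlation. The median was 1.08 without CNV_DSS replicate 17. Of 10 genes of MHC class II presentation, 9 rose and 0 fell (9 and 0 adjusted over the list alone, median 4.20), among them Ciita (4.71 ± 0.635) and H2-Eb1 (5.08 ± 0.781). Genes of MHC class II presentation had a camera adjusted p = 3.55e-05 and adjusted p = 0.417 with an estimated correlation. Of 31 cytokines and chemokines, 24 rose and 0 fell (24 and 2 adjusted over the list alone, median 4.85, or 3.92 with genes at 0 counts set to their bound), among them Il1a (9.03 ± 0.908) and Ccl4 (8.65 ± 0.922). Cytokines and chemokines had a camera adjusted p = 2.63e-09 and adjusted p = 0.396 with an estimated correlation. The median was 2.90 without CNV_DSS replicate 17. Of 28 antimicrobial and mucosal defence genes, 18 rose and 4 fell (18 and 4 adjusted over the list alone, median 2.29), among them Saa3 (6.34 ± 0.663) and Itln1 (-4.003 ± 0.371). Antimicrobial and mucosal defence genes had a camera adjusted p = 0.000231 and adjusted p = 0.417 with an estimated correlation. The median was 1.22 without CNV_DSS replicate 17. Of 39 genes of microbial sensing and NF-kB, 18 rose and 2 fell (19 and 2 adjusted over the list alone, median 0.48), among them Tlr2 (2.31 ± 0.216) and Icam1 (4.46 ± 0.526). Genes of microbial sensing and NF-kB had a camera adjusted p = 0.000156 and adjusted p = 0.437 with an estimated correlation. The median was 0.23 without CNV_DSS replicate 17. Of 12 oxidase system genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.58), among them Nos2 (5.85 ± 0.584) and Duox2 (1.18 ± 0.348). Oxidase system genes had a camera adjusted p = 0.0843.

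CNV_DSS replicate 17 stood apart in several of these lists. Its mean level in log2 CPM was 7.44 over interferon-stimulated genes, against 5.30 and 5.42 in the other CNV_DSS libraries and 3.67 to 4.58 in CNV. Over genes of MHC class II presentation it was 7.06, against 4.84 and 5.07, and over cytokines and chemokines 4.67, against 2.999 and 2.93.

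Markers of other cell types rose beside these lists. Of 12 leukocyte markers, 12 rose and 0 fell (12 and 0 adjusted over the list alone, median 3.97), among them Cd53 (6.18 ± 0.875). Leukocyte markers had a camera adjusted p = 2.63e-09 and adjusted p = 0.396 with an estimated correlation. Of 17 macrophage and dendritic cell markers, 17 rose and 0 fell (17 and 0 adjusted over the list alone, median 4.98, or 4.71 with genes at 0 counts set to their bound), among them Lyz2 (6.20 ± 0.538) and Csf1r (6.74 ± 0.679). Macrophage and dendritic cell markers had a camera adjusted p = 9.62e-17 and adjusted p = 0.22 with an estimated correlation. Of 14 neutrophil markers, 14 rose and 0 fell (14 and 0 adjusted over the list alone, median 12, or 9.05 with genes at 0 counts set to their bound), among them Mmp9 (8.28 ± 0.823). Neutrophil markers had a camera adjusted p = 1.31e-13 and adjusted p = 0.278 with an estimated correlation. Of 15 fibroblast markers, 14 rose and 1 fell (14 and 1 adjusted over the list alone, median 4.45), among them Col1a2 (5.01 ± 0.575) and Vim (3.90 ± 0.485). Fibroblast markers had a camera adjusted p = 2.46e-12 and adjusted p = 0.22 with an estimated correlation. In CNV_DSS replicate 17 the mean log2 CPM was 6.29 over neutrophil and 4.87 over leukocyte markers, against at most 3.94 and 3.12 in the other CNV_DSS libraries.

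Of 18 T cell and intraepithelial lymphocyte markers, 14 rose and 0 fell (16 and 0 adjusted over the list alone, median 2.34), among them Cd8a (3.23 ± 0.385) and Gzma (6.56 ± 0.929). T cell and intraepithelial lymphocyte markers had a camera adjusted p = 1.11e-07 and adjusted p = 0.391 with an estimated correlation. Of 10 B cell and plasma cell markers, 10 rose and 0 fell (10 and 0 adjusted over the list alone, median 2.40), among them Igj (5.57 ± 0.51). B cell and plasma cell markers had a camera adjusted p = 6.2e-05 and adjusted p = 0.417 with an estimated correlation. Of 13 endothelial markers, 7 rose and 0 fell (8 and 0 adjusted over the list alone, median 2.26), among them Cdh5 (2.90 ± 0.471). Endothelial markers had a camera adjusted p = 0.00265 and adjusted p = 0.417 with an estimated correlation. Of 9 smooth muscle markers, 6 rose and 1 fell (7 and 1 adjusted over the list alone, median 1.78), among them Acta2 (3.05 ± 0.394). Smooth muscle markers had a camera adjusted p = 0.0166 and adjusted p = 0.443 with an estimated correlation.

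Lists of regeneration, of YAP targets and of metabolism went both ways. Since markers of other cell types rose as well, these changes cannot be assigned to epithelium alone. Of 25 regenerative epithelium genes, 20 rose and 0 fell (20 and 1 adjusted over the list alone, median 1.58), among them Ly6d (6.03 ± 0.507) and Mmp7 (6.18 ± 0.556). Regenerative epithelium genes had a camera adjusted p = 2.56e-08 and adjusted p = 0.22 with an estimated correlation. The median was 1.03 without CNV_DSS replicate 17. Of 15 YAP targets, 6 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.56), among them Axl (5.96 ± 0.783). YAP targets had a camera adjusted p = 0.0136 and adjusted p = 0.278 with an estimated correlation. The median was 0.37 without CNV_DSS replicate 17. Of 29 hypoxia and glycolysis genes, 15 rose and 0 fell (16 and 0 adjusted over the list alone, median 0.66), among them Slc16a3 (3.28 ± 0.279). Hypoxia and glycolysis genes had a camera adjusted p = 3.12e-06 and adjusted p = 0.437 with an estimated correlation. The median was 0.39 without CNV_DSS replicate 17. Of 56 xenobiotic metabolism genes, 6 rose and 23 fell (6 and 23 adjusted over the list alone, median -0.48), among them Sult1a1 (-2.44 ± 0.179) and Gstt1 (-2.16 ± 0.192). Xenobiotic metabolism genes had a camera adjusted p = 7.59e-05 and adjusted p = 0.437 with an estimated correlation. Of 67 oxidative phosphorylation genes, 0 rose and 28 fell (0 and 29 adjusted over the list alone, median -0.35), among them Atp5e (-1.66 ± 0.244). Oxidative phosphorylation genes had a camera adjusted p = 1.59e-05 and adjusted p = 0.581 with an estimated correlation.

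Of 18 tuft cell markers, 1 rose and 10 fell (2 and 10 adjusted over the list alone, median -0.96), among them Trpm5 (-1.98 ± 0.231) and Pou2f3 (-1.47 ± 0.282). Tuft cell markers had a camera adjusted p = 0.000458 and adjusted p = 0.417 with an estimated correlation. Of 7 genes of distal-colon position, 0 rose and 4 fell (1 and 6 adjusted over the list alone, median -1.46), among them Hoxb13 (-1.38 ± 0.245) and Hoxd12 (-3.52 ± 0.734). Genes of distal-colon position had a camera adjusted p = 0.018 and adjusted p = 0.455 with an estimated correlation. That camera call was lost without CNV replicate 6 (adjusted p = 0.0515). The median was -2.35 without CNV_DSS replicate 16. The water channel Aqp8 (-1.49 ± 0.339), the anion exchanger Slc26a3 (-1.52 ± 0.296) and the carbonic anhydrase Car4 (-2.20 ± 0.362) fell. Over all 40 absorptive colonocyte genes, 6 rose and 14 fell (6 and 14 adjusted over the list alone, median -0.17). Camera did not call that list (adjusted p = 0.0886). The mucin Muc2 stood at 0.45 ± 0.229, adjusted p = 0.145. DSS changed 5386 genes in CNV, 2760 higher and 2626 lower (2606 and 2719 with upper-quartile factors), of which 2470 by more than 2-fold. Camera called 20 of 36 lists in this comparison, and 0 of those calls held with an estimated correlation.

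**Figure D2:**
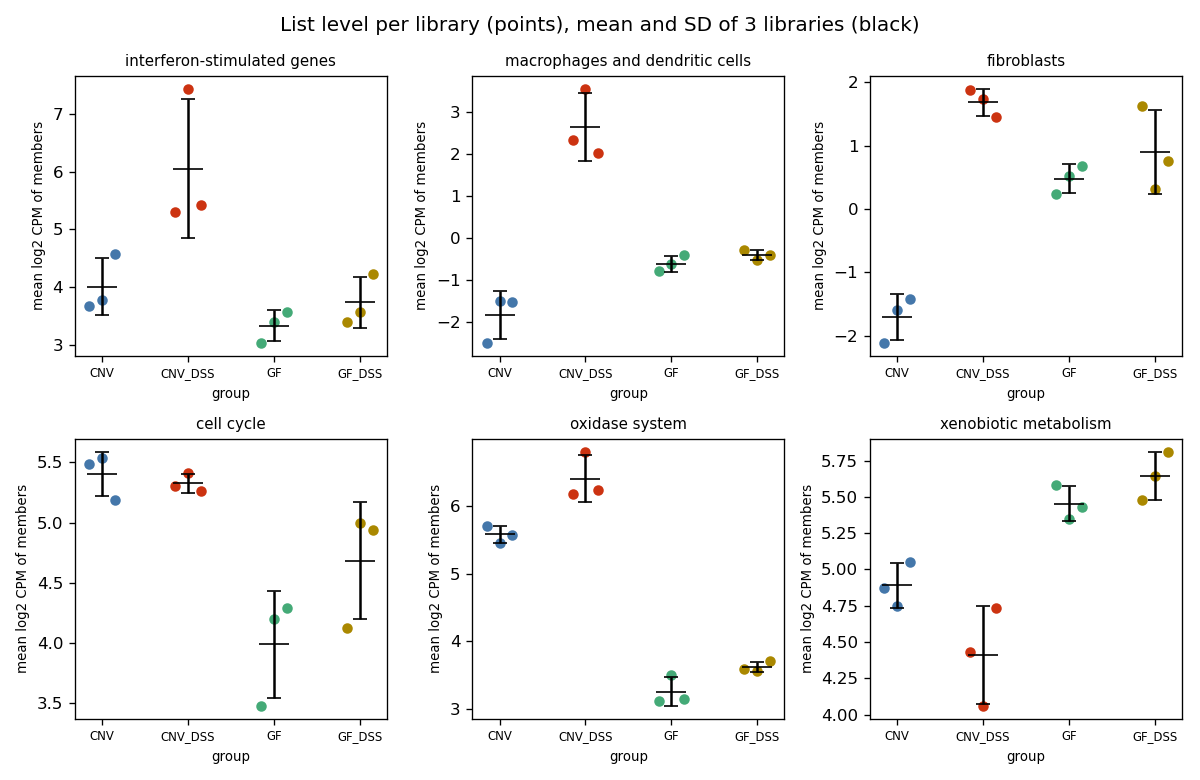
Mean log2 CPM (vertical axis) over the tested members of 6 lists, by group, with a coloured point per library and the mean ± SD of 3 libraries in black. Oxidase genes lie at or below 3.70 in the 6 germ-free libraries and at or above 5.46 in the other 6.

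The next question was how DSS changed the epithelium of mice without microbes. The acute phase protein Saa3 rose by 3.69 ± 0.642, adjusted p = 0.00654, and the malic enzyme Me1 by 3.52 ± 0.515. The clock output gene Dbp fell by 3.46 ± 0.261 (adjusted p = 3.96e-05) and the immediate-early gene Fosb fell by 3.13 ± 0.36. Further rises were Lpo (3.32 ± 0.488), Aldh1a3 (3.27 ± 0.438), Atg9b (3.16 ± 0.698), Khdc1a (3.16 ± 0.704), Myl7 (3.03 ± 0.638) and Wfdc18 (2.77 ± 0.354), and the chemokine Cxcl5 (2.71 ± 0.727). Khdc1a shares 43.5% of its 50-base sequences with another gene, so its reads are uncertain. Prss22 had 2 counts in GF and a ratio of 8.4 (95% counting interval 2.21 to 71.2). Further falls were Ctcfl (-2.77 ± 0.481), Usp2 (-2.75 ± 0.33), St8sia5 (-2.65 ± 0.643), Ppp1r16b (-2.08 ± 0.332) and Pura (-2.06 ± 0.209).

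Of 40 cell cycle genes, 12 rose and 0 fell (24 and 0 adjusted over the list alone, median 0.78), among them Gins2 (0.97 ± 0.197) and Mcm5 (0.80 ± 0.188). Cell cycle genes had a camera adjusted p = 6.65e-10 and adjusted p = 0.977 with an estimated correlation. The groups overlapped: mean log2 CPM over the list was 4.12 in GF_DSS replicate 4 and 4.997 and 4.94 in replicates 5 and 6, against 3.48 in GF replicate 2 and 4.20 and 4.29 in replicates 3 and 4. Of 25 regenerative epithelium genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone, median 1.11, or 0.60 with genes at 0 counts set to their bound), among them Ereg (2.62 ± 0.47) and Ly6d (1.96 ± 0.515). Regenerative epithelium genes had a camera adjusted p = 0.00318 and adjusted p = 0.839 with an estimated correlation. The median was 0.72 without GF replicate 3 and 0.66 without GF_DSS replicate 5. Of 23 dissociation and immediate-early genes, 0 rose and 11 fell (0 and 14 adjusted over the list alone, median -1.24), among them Fos (-1.25 ± 0.113) and Jun (-1.22 ± 0.121). Dissociation and immediate-early genes had a camera adjusted p = 1.75e-20 and adjusted p = 0.0623 with an estimated correlation. Mean log2 CPM over the list was 6.31 to 6.44 in GF and 5.28 to 5.42 in GF_DSS. It was 5.68 to 5.89 in CNV and 5.80 to 6.54 in CNV_DSS. A difference in sample handling between GF and GF_DSS was not tested. Of 17 circadian clock genes, 0 rose and 8 fell (4 and 9 adjusted over the list alone, median -0.96), among them Per2 (-1.73 ± 0.218) and Nr1d1 (-1.29 ± 0.187). Circadian clock genes had a camera adjusted p = 1.22e-05 and adjusted p = 0.0623 with an estimated correlation. The labels give no time of day of collection for any group. Of 7 genes of distal-colon position, 0 rose and 5 fell (0 and 6 adjusted over the list alone, median -2.21), among them Hoxd11 (-2.69 ± 0.565) and Hoxd13 (-2.21 ± 0.578). Genes of distal-colon position had a camera adjusted p = 2.67e-05 and adjusted p = 0.677 with an estimated correlation.

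Camera called no list of immune cells or defence genes here. Of 40 interferon-stimulated genes, 0 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.36). Interferon-stimulated genes had a camera adjusted p = 0.219. Of 12 leukocyte markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.91). Leukocyte markers had a camera adjusted p = 0.149. Of 17 macrophage and dendritic cell markers, 0 rose and 2 fell (0 and 2 adjusted over the list alone, median 0.39), among them Cx3cr1 (-2.65 ± 0.399) and Cd68 (-1.25 ± 0.308). Macrophage and dendritic cell markers had a camera adjusted p = 0.886. Of 10 B cell and plasma cell markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone, median 1.42). B cell and plasma cell markers had a camera adjusted p = 0.057. Of 14 neutrophil markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone, median 1.25, or 0.67 with genes at 0 counts set to their bound). Neutrophil markers had a camera adjusted p = 0.441. GF_DSS replicate 4 stood apart, with a mean log2 CPM of 2.55 over leukocyte markers against 1.53 and 1.43 in replicates 5 and 6. Over B cell and plasma cell markers it was 1.46 against -0.11 and -0.08, and over fibroblast markers 1.62 against 0.32 and 0.76. Reg3g stood at 2.32 ± 1.77, adjusted p = 0.426, and Nos2 at 0.64 ± 1.01, adjusted p = 0.723. DSS changed 1629 genes in GF, 673 higher and 956 lower (649 and 618 without GF_DSS replicate 4), of which 580 by more than 2-fold. That count was 741 without GF replicate 2, 810 without GF replicate 4, 394 without GF_DSS replicate 5 and 597 without GF_DSS replicate 6.

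The DSS changes in CNV and in GF were then set against each other across genes, which are not independent replicates. Their correlation was r = 0.36 (Spearman rho = 0.323), and 0.228 with no filter on low counts. In both, 201 genes rose, where independent lists would share 123.7. For falls the shared number was 334 against 167.2. In opposite directions, 106 genes changed, against 293.4.

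The difference between these DSS changes was tested directly, with positive values where the change was more positive in germ-free mice. It was positive for Mptx1 (9.91 ± 0.756, adjusted p = 0.000108), Mptx2 (9.30 ± 0.733), Slc30a10 (7.67 ± 0.304), Pla2g4c (5.48 ± 0.59) and Tppp3 (4.84 ± 0.509). It was negative for the granulocyte growth factor receptor Csf3r (-8.50 ± 1.21, adjusted p = 0.00215), the Fc receptor Fcgr3 (-8.41 ± 1.65) and the tryptophan-degrading enzyme Ido1 (-8.40 ± 1.63). Gp49a (-9.57 ± 2.76) and Lilrb4 (-9.09 ± 2.65) were also negative, but share 15.8% and 39.8% of their 50-base sequences with another gene, so their reads are uncertain. Levels of Csf3r were 0.235 ± 0.0237 CPM in CNV, 51.1 ± 53.9 in CNV_DSS, 1.06 ± 0.563 in GF and 0.602 ± 0.209 in GF_DSS (SD, n = 3). Pla2g4c was already far lower in GF than in CNV without DSS. Its positive difference therefore does not show that germ-free mice kept a high level under DSS.

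Of 17 macrophage and dendritic cell markers, 0 had a positive and 14 a negative difference (0 and 15 adjusted over the list alone, median -4.81), among them C1qb (-5.11 ± 0.694) and Csf1r (-6.37 ± 0.89). Macrophage and dendritic cell markers had a camera adjusted p = 2.19e-18 and adjusted p = 0.148 with an estimated correlation. Of 12 leukocyte markers, 0 had a positive and 11 a negative difference (0 and 11 adjusted over the list alone, median -3.38), among them Cd53 (-5.13 ± 1.17). Leukocyte markers had a camera adjusted p = 4.91e-08 and adjusted p = 0.372 with an estimated correlation. Of 15 fibroblast markers, 1 had a positive and 11 a negative difference (1 and 14 adjusted over the list alone, median -3.89), among them Col1a2 (-4.30 ± 0.727). Fibroblast markers had a camera adjusted p = 6.42e-11 and adjusted p = 0.148 with an estimated correlation. Of 18 T cell and intraepithelial lymphocyte markers, 0 had a positive and 11 a negative difference (0 and 13 adjusted over the list alone, median -2.38), among them Gzma (-8.29 ± 1.15). T cell and intraepithelial lymphocyte markers had a camera adjusted p = 1.37e-08 and adjusted p = 0.332 with an estimated correlation. Fibroblast and T cell markers already lay higher in GF than in CNV without DSS (medians 2.59 and 2.25). Under DSS, camera called neither list between GF_DSS and CNV_DSS (medians -0.53 and -0.07, adjusted p = 0.0588 and 0.744). Their negative differences therefore hold a higher start in GF and do not show a lower level in GF_DSS.

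Of 10 genes of MHC class II presentation, 0 had a positive and 8 a negative difference (0 and 8 adjusted over the list alone, median -4.19), among them Cd74 (-5.17 ± 1.18). Genes of MHC class II presentation had a camera adjusted p = 7.97e-06 and adjusted p = 0.389 with an estimated correlation. Of 40 interferon-stimulated genes, 0 had a positive and 9 a negative difference (0 and 15 adjusted over the list alone, median -1.77), among them Igtp (-3.35 ± 0.884). Interferon-stimulated genes had a camera adjusted p = 8.14e-07 and adjusted p = 0.517 with an estimated correlation. The median was -0.82 without CNV_DSS replicate 17. Of 18 tuft cell markers, 7 had a positive and 0 a negative difference (11 and 0 adjusted over the list alone, median 1.20), among them Trpm5 (2.58 ± 0.322). Tuft cell markers had a camera adjusted p = 9.7e-06 and adjusted p = 0.372 with an estimated correlation. Of 56 xenobiotic metabolism genes, 15 had a positive and 0 a negative difference (21 and 0 adjusted over the list alone, median 0.56), among them Sult1a1 (2.32 ± 0.243). Xenobiotic metabolism genes had a camera adjusted p = 1.03e-06 and adjusted p = 0.389 with an estimated correlation. Of 40 cell cycle genes, 6 had a positive and 0 a negative difference (6 and 0 adjusted over the list alone, median 0.91), among them Gins2 (1.25 ± 0.271). Cell cycle genes had a camera adjusted p = 1.07e-06 and adjusted p = 0.517 with an estimated correlation. They lay lower in GF than in CNV without DSS (median -1.40), and DSS in CNV left their median at -0.13 (0 rose and 2 fell). GF_DSS still lay below CNV_DSS (0 rose and 16 fell, median -0.53, or -0.32 without GF_DSS replicate 4). Camera gave that comparison an adjusted p = 9.66e-05, and 0.545 with an estimated correlation.

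The dissociation and immediate-early list holds genes that respond to sample handling. Of 23 dissociation and immediate-early genes, 0 had a positive and 13 a negative difference (0 and 15 adjusted over the list alone, median -1.68). Dissociation and immediate-early genes had a camera adjusted p = 1.29e-10 and adjusted p = 0.148 with an estimated correlation. The median was -0.98 without CNV_DSS replicate 17.

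The difference passed the test for 2538 genes, 1217 positive and 1321 negative (1313 and 1174 with upper-quartile factors). Without CNV replicate 4, GF_DSS replicate 5 or GF_DSS replicate 6 the number was 1398, 1364 or 1537.

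GF was compared with CNV to ask how the epithelium differs without microbes when no DSS is given. The dual oxidase Duox2 fell by 4.17 ± 0.397 (adjusted p = 4.28e-05), its maturation factor Duoxa2 fell by 4.26 ± 0.41 and the nitric oxide synthase Nos2 fell by 5.25 ± 0.775. Retnlb, a goblet cell protein, went from 652 ± 172 CPM in CNV to 12 ± 12.5 CPM in GF (SD, n = 3), with an edgeR adjusted p = 0.00622. Dbp rose by 7.39 ± 0.339, adjusted p = 2.83e-07, from 0.762 ± 0.0176 to 128 ± 25.7 CPM (SD, n = 3). Other large falls were Pla2g4c (-6.79 ± 0.461), the calcium channel Trpv6 (-4.56 ± 0.356), Itln1 (-4.41 ± 0.396) and Me1 (-4.35 ± 0.521). The imprinted noncoding RNAs Rian (-5.30 ± 0.74) and Meg3 (-4.28 ± 0.431) also fell.

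Further rises were Csl (5.14 ± 0.345), Klk1b4 (4.80 ± 0.335), Aldoart1 (4.73 ± 0.271), Sprr2b (4.19 ± 0.381) and Ly6i (4.03 ± 0.846), the amino acid transporter Slc7a9 (3.74 ± 0.298), Saa2 (4.38 ± 0.415), the metallothionein Mt2 (4.27 ± 0.247) and the glycolytic enzyme Eno1 (4.24 ± 0.397). Eno1, Mt2, Saa2, Dbp, Klk1b4 and Sprr2b share 67.9%, 45.5%, 31.8%, 27.5%, 21.3% and 14.1% of their 50-base sequences with another gene. Processed pseudogenes were higher in both germ-free groups, with a median of 1.52 without DSS, so these rises are uncertain. The percentages count identical 50-base sequences only. For the other rises, among them Csl and Aldoart1, reads from a similar but not identical gene are therefore not excluded.

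Of 40 cell cycle genes, 0 rose and 38 fell (0 and 38 adjusted over the list alone, median -1.40), among them Mcm5 (-1.99 ± 0.192) and Gins2 (-1.73 ± 0.199). Cell cycle genes had a camera adjusted p = 1.29e-22 and adjusted p = 0.331 with an estimated correlation. Of 23 stem cell and Wnt target genes, 1 rose and 9 fell (1 and 10 adjusted over the list alone, median -0.51), among them Ephb3 (-1.13 ± 0.147). Stem cell and Wnt target genes had a camera adjusted p = 0.00586 and adjusted p = 0.574 with an estimated correlation. Of 26 goblet cell and mucus genes, 3 rose and 11 fell (3 and 12 adjusted over the list alone, median -0.44), among them Spink4 (-3.23 ± 0.24) and Spdef (-1.14 ± 0.213). Goblet cell and mucus genes had a camera adjusted p = 0.0308 and adjusted p = 0.574 with an estimated correlation. That camera call was lost without CNV replicate 5 (adjusted p = 0.139) and without GF replicate 3 (adjusted p = 0.109). The median was -0.18 without CNV replicate 5. Of 31 unfolded protein response genes, 2 rose and 14 fell (3 and 14 adjusted over the list alone, median -0.38), among them Hyou1 (-1.09 ± 0.18). Unfolded protein response genes had a camera adjusted p = 0.00169 and adjusted p = 0.574 with an estimated correlation.

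Of 12 oxidase system genes, 1 rose and 10 fell (1 and 11 adjusted over the list alone, median -2.54), among them Duox1 (-2.60 ± 0.335) and Gpx2 (-2.69 ± 0.354). Oxidase system genes had a camera adjusted p = 2.51e-10 and adjusted p = 0.1 with an estimated correlation. Of 28 antimicrobial and mucosal defence genes, 1 rose and 9 fell (1 and 9 adjusted over the list alone, median -1.16, or -0.43 with genes at 0 counts set to their bound), among them Pla2g2a (-3.93 ± 0.352). Antimicrobial and mucosal defence genes had a camera adjusted p = 0.00169 and adjusted p = 0.541 with an estimated correlation. The median was -1.87 without CNV replicate 4, -0.47 without CNV replicate 6 and -1.94 without GF replicate 2. Of 25 cholesterol synthesis genes, 0 rose and 7 fell (0 and 7 adjusted over the list alone, median -0.36), among them Acat2 (-1.24 ± 0.176) and Fdps (-1.22 ± 0.212). Cholesterol synthesis genes had a camera adjusted p = 0.000707 and adjusted p = 0.574 with an estimated correlation. The median was -0.22 without GF replicate 4. Of 40 interferon-stimulated genes, 0 rose and 2 fell (0 and 1 adjusted over the list alone, median -0.57), among them Mx1 (-2.78 ± 0.475). Interferon-stimulated genes had a camera adjusted p = 0.0235 and adjusted p = 0.725 with an estimated correlation. That camera call was lost without CNV replicate 6 (adjusted p = 0.308) and without GF replicate 2 (adjusted p = 0.0667). The median was -0.25 without CNV replicate 6.

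Of 30 genes of the DNA methylation machinery, 2 rose and 9 fell (2 and 10 adjusted over the list alone, median -0.12), among them Dnmt1 (-1.28 ± 0.156) and Uhrf1 (-2.50 ± 0.25). Genes of the DNA methylation machinery had a camera adjusted p = 0.0234 and adjusted p = 0.19 with an estimated correlation. The median was -0.21 without CNV replicate 5, -0.22 without CNV replicate 6 and -0.24 without GF replicate 3. Dnmt1 copies methylation marks at replication and Uhrf1 recruits it. In the same comparison 38 of 40 cell cycle genes fell (median -1.40). The falls of Dnmt1 and Uhrf1 therefore cannot be told apart from that of the cell cycle genes. The de novo methyltransferases Dnmt3a and Dnmt3b stood at -0.25 ± 0.133, adjusted p = 0.178, and -0.06 ± 0.276, adjusted p = 0.892. Of the demethylating enzymes, Tet2 fell (-0.58 ± 0.153, adjusted p = 0.0126) and Tet3 stood at 0.20 ± 0.123, adjusted p = 0.248.

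Of 56 xenobiotic metabolism genes, 17 rose and 6 fell (18 and 6 adjusted over the list alone, median 0.47), among them Gsta2 (2.96 ± 0.251) and Abcc2 (3.26 ± 0.395). Xenobiotic metabolism genes had a camera adjusted p = 0.000707 and adjusted p = 0.574 with an estimated correlation. The median was 0.28 without CNV replicate 5 and 0.71 without CNV replicate 6. Of 40 absorptive colonocyte genes, 14 rose and 3 fell (16 and 3 adjusted over the list alone, median 0.25), among them Car1 (1.997 ± 0.266) and Car2 (1.26 ± 0.147). Absorptive colonocyte genes had a camera adjusted p = 0.00472 and adjusted p = 0.541 with an estimated correlation. The median was 0.09 without CNV replicate 5, 0.46 without CNV replicate 6 and 0.16 without GF replicate 2. Of 31 fatty acid oxidation and PPAR target genes, 11 rose and 1 fell (13 and 2 adjusted over the list alone, median 0.36), among them Ppara (1.14 ± 0.235). Fatty acid oxidation and PPAR target genes had a camera adjusted p = 0.00472 and adjusted p = 0.541 with an estimated correlation. Of 67 oxidative phosphorylation genes, 17 rose and 2 fell (16 and 2 adjusted over the list alone, median 0.22), among them Uqcrb (1.35 ± 0.194). Oxidative phosphorylation genes had a camera adjusted p = 0.00433 and adjusted p = 0.686 with an estimated correlation. That camera call was lost without GF replicate 2 (adjusted p = 0.153). The median was 0.08 without GF replicate 2 and 0.34 without GF replicate 3. Of 19 bile acid and steroid hormone genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.58), among them Cyp11a1 (4.90 ± 0.754). Bile acid and steroid hormone genes had a camera adjusted p = 0.00397 and adjusted p = 0.118 with an estimated correlation.

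Of 17 circadian clock genes, 11 rose and 4 fell (11 and 4 adjusted over the list alone, median 1.10), among them Tef (3.37 ± 0.235) and Nr1d1 (2.04 ± 0.192). Circadian clock genes had a camera adjusted p = 9.33e-06 and adjusted p = 0.1 with an estimated correlation. Markers of other cell types were compared too. Of 18 T cell and intraepithelial lymphocyte markers, 14 rose and 0 fell (15 and 0 adjusted over the list alone, median 2.25), among them Cd3e (3.07 ± 0.467) and Cd8a (2.53 ± 0.394). T cell and intraepithelial lymphocyte markers had a camera adjusted p = 1.14e-07 and adjusted p = 0.331 with an estimated correlation. Of 15 fibroblast markers, 12 rose and 1 fell (12 and 1 adjusted over the list alone, median 2.59), among them Col1a2 (3.73 ± 0.586). Fibroblast markers had a camera adjusted p = 9.33e-06 and adjusted p = 0.331 with an estimated correlation. Of 9 smooth muscle markers, 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 2.37), among them Acta2 (3.30 ± 0.399). Smooth muscle markers had a camera adjusted p = 0.00149 and adjusted p = 0.506 with an estimated correlation. Of 17 macrophage and dendritic cell markers, 5 rose and 1 fell (6 and 1 adjusted over the list alone, median 1.61, or 1.68 with genes at 0 counts set to their bound), among them Cx3cr1 (3.17 ± 0.44). Macrophage and dendritic cell markers had a camera adjusted p = 0.00586 and adjusted p = 0.574 with an estimated correlation.

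Of 12 leukocyte markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone, median 1.17). Leukocyte markers had a camera adjusted p = 0.0308 and adjusted p = 0.636 with an estimated correlation. That camera call was lost without CNV replicate 4 (adjusted p = 0.068), without GF replicate 3 (adjusted p = 0.0634) and without GF replicate 4 (adjusted p = 0.0731). The median was 0.75 without CNV replicate 4. Of 13 endothelial markers, 6 rose and 0 fell (7 and 1 adjusted over the list alone, median 1.29). Endothelial markers had a camera adjusted p = 0.0493 and adjusted p = 0.574 with an estimated correlation. That camera call was lost without CNV replicate 4 (adjusted p = 0.0844), without CNV_DSS replicate 16 (adjusted p = 0.0512), without CNV_DSS replicate 17 (adjusted p = 0.0575), without GF replicate 3 (adjusted p = 0.0982) and without GF_DSS replicate 6 (adjusted p = 0.0506). Of 10 B cell and plasma cell markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.10). B cell and plasma cell markers had a camera adjusted p = 0.757. Of 14 neutrophil markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone, median 0, or 0.46 with genes at 0 counts set to their bound). Neutrophil markers had a camera adjusted p = 0.866.

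Of 23 dissociation and immediate-early genes, 10 rose and 2 fell (12 and 3 adjusted over the list alone, median 0.49). Dissociation and immediate-early genes had a camera adjusted p = 0.00296 and adjusted p = 0.541 with an estimated correlation.

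Between GF and CNV 4536 genes changed, 2258 higher and 2278 lower (2389 and 2131 with upper-quartile factors), and the number was 3015 without CNV replicate 4. Total counts were lower in each GF library than in each CNV library, so genes of low level were measured less precisely in GF.

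GF_DSS was compared with CNV_DSS to ask how the epithelium under DSS differs without microbes. S100a8 fell by 11.36 ± 1.15 (adjusted p = 9.95e-05) and S100a9 fell by 10.75 ± 1.18. Further falls were Nos2 (-10.47 ± 0.734), Ptgs2 (-10.17 ± 1.06), Irg1 (-9.85 ± 1.18), Lrg1 (-9.82 ± 0.826), Clec4e (-9.29 ± 0.899), Cxcl2 (-9.10 ± 1.03) and Reg3b (-9.01 ± 1.81). Retnlg had 0 counts in GF_DSS and was at least 4000-fold lower. Mptx2 rose by 11.19 ± 0.624, adjusted p = 3.53e-07, and Mptx1 by 8.83 ± 0.636. Further rises were Klk1b3 (7.30 ± 0.346), Sprr2b (6.75 ± 0.425), Klk1b4 (6.70 ± 0.385), Csl (6.24 ± 0.343), Slc30a10 (6.19 ± 0.242) and Slc37a2 (5.41 ± 0.603), and the amino acid transporter Slc6a19 (5.74 ± 0.37). Klk1b3, Klk1b4, Mptx2, Mptx1 and Sprr2b share 21.3%, 21.3%, 18%, 17.9% and 14.1% of their 50-base sequences with another gene. Processed pseudogenes had a median of 1.79 under DSS, so the size of these rises is uncertain. Mptx1 and Mptx2 also fell with DSS in CNV, a comparison without germ-free libraries. That fall does not rest on how the germ-free libraries were counted. For Csl and the other rises, reads from a similar but not identical gene are not excluded.

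Of 40 interferon-stimulated genes, 0 rose and 35 fell (0 and 37 adjusted over the list alone, median -2.35), among them Ifit2 (-5.94 ± 0.821). Interferon-stimulated genes had a camera adjusted p = 4.87e-10 and adjusted p = 0.432 with an estimated correlation. The median was -1.41 without CNV_DSS replicate 17. Of 31 cytokines and chemokines, 0 rose and 25 fell (0 and 25 adjusted over the list alone, median -4.95), among them Il1b (-8.45 ± 0.83) and Ccl4 (-7.22 ± 0.763). Cytokines and chemokines had a camera adjusted p = 3.12e-10 and adjusted p = 0.243 with an estimated correlation. The median was -3.15 without CNV_DSS replicate 17. Of 14 neutrophil markers, 0 rose and 14 fell (0 and 14 adjusted over the list alone, median -8.79, or -8.36 with genes at 0 counts set to their bound), among them Mmp9 (-8.29 ± 0.768). Neutrophil markers had a camera adjusted p = 3.57e-11 and adjusted p = 0.243 with an estimated correlation. Of 17 macrophage and dendritic cell markers, 0 rose and 16 fell (0 and 17 adjusted over the list alone, median -2.93), among them Itgam (-4.52 ± 0.558) and Lyz2 (-3.63 ± 0.448). Macrophage and dendritic cell markers had a camera adjusted p = 2.66e-10 and adjusted p = 0.243 with an estimated correlation. Of 12 leukocyte markers, 0 rose and 9 fell (0 and 11 adjusted over the list alone, median -2), among them Cd53 (-3.62 ± 0.714). Leukocyte markers had a camera adjusted p = 0.00158 and adjusted p = 0.505 with an estimated correlation. The median was -1.16 without CNV_DSS replicate 17. Markers of T cells, B cells, fibroblasts, endothelium and smooth muscle were not called by camera here. Their medians were -0.07, -0.45, -0.53, -0.58 and 0.30, with adjusted p = 0.744, 0.0591, 0.0588, 0.158 and 0.693.

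Of 28 antimicrobial and mucosal defence genes, 2 rose and 18 fell (2 and 20 adjusted over the list alone, median -2.74), among them Ltf (-8.94 ± 0.807) and Pla2g2a (-4.27 ± 0.33). Antimicrobial and mucosal defence genes had a camera adjusted p = 6.8e-08 and adjusted p = 0.243 with an estimated correlation. Of 12 oxidase system genes, 0 rose and 10 fell (1 and 10 adjusted over the list alone, median -2.19), among them Duox2 (-5.41 ± 0.416) and Cyba (-1.98 ± 0.183). Oxidase system genes had a camera adjusted p = 6.38e-10 and adjusted p = 0.197 with an estimated correlation. Of 31 unfolded protein response genes, 0 rose and 24 fell (1 and 26 adjusted over the list alone, median -0.77), among them Xbp1 (-0.99 ± 0.107) and Hspa5 (-1.33 ± 0.18). Unfolded protein response genes had a camera adjusted p = 1.13e-09 and adjusted p = 0.243 with an estimated correlation. Of 25 regenerative epithelium genes, 1 rose and 18 fell (2 and 20 adjusted over the list alone, median -1.85), among them Mmp7 (-5.22 ± 0.498). Regenerative epithelium genes had a camera adjusted p = 1.5e-07 and adjusted p = 0.243 with an estimated correlation.

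Of 56 xenobiotic metabolism genes, 34 rose and 2 fell (38 and 2 adjusted over the list alone, median 1.07), among them Sult1a1 (3.50 ± 0.187) and Aldh1a1 (3.81 ± 0.299). Xenobiotic metabolism genes had a camera adjusted p = 5.58e-15 and adjusted p = 0.243 with an estimated correlation. Of 67 oxidative phosphorylation genes, 41 rose and 0 fell (48 and 0 adjusted over the list alone, median 0.44), among them Ndufb2 (0.88 ± 0.133). Oxidative phosphorylation genes had a camera adjusted p = 6.8e-08 and adjusted p = 0.505 with an estimated correlation. Of 31 fatty acid oxidation and PPAR target genes, 20 rose and 1 fell (21 and 1 adjusted over the list alone, median 0.63), among them Ppara (1.85 ± 0.236) and Hadh (0.92 ± 0.127). Fatty acid oxidation and PPAR target genes had a camera adjusted p = 1.84e-06 and adjusted p = 0.243 with an estimated correlation. Of 18 tuft cell markers, 11 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.91), among them Trpm5 (1.47 ± 0.228). Tuft cell markers had a camera adjusted p = 0.00222 and adjusted p = 0.411 with an estimated correlation. Of 23 dissociation and immediate-early genes, 1 rose and 11 fell (1 and 12 adjusted over the list alone, median -0.59). Dissociation and immediate-early genes had a camera adjusted p = 0.00158 and adjusted p = 0.357 with an estimated correlation. The median was -0.37 without CNV_DSS replicate 17. Muc2 fell by 1.44 ± 0.233 (adjusted p = 0.000576).

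Between GF_DSS and CNV_DSS 5564 genes changed, 2639 higher and 2925 lower. With upper-quartile factors 3090 were higher and 2420 lower, and 2972 and 2693 when only the groups compared were fitted. Across genes, the germ-free changes without and under DSS had r = 0.356 (rho = 0.387). In both, 1035 genes rose, against 396.8 for independent lists, and 920 fell, against 443.7. In opposite directions, 224 changed, against 840.1. Processed pseudogenes were higher in both germ-free groups too, with medians of 1.52 and 1.79. Oaz1 had 1 count in CNV and 150 in GF (ratio 223, 95% counting interval 39.4 to 8870), and 3 counts in CNV_DSS and 521 in GF_DSS (ratio 123, 41.9 to 599). A difference in how the germ-free libraries were counted would be shared by both changes, so the overlap does not single out the germ-free state.

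**Figure D3:**
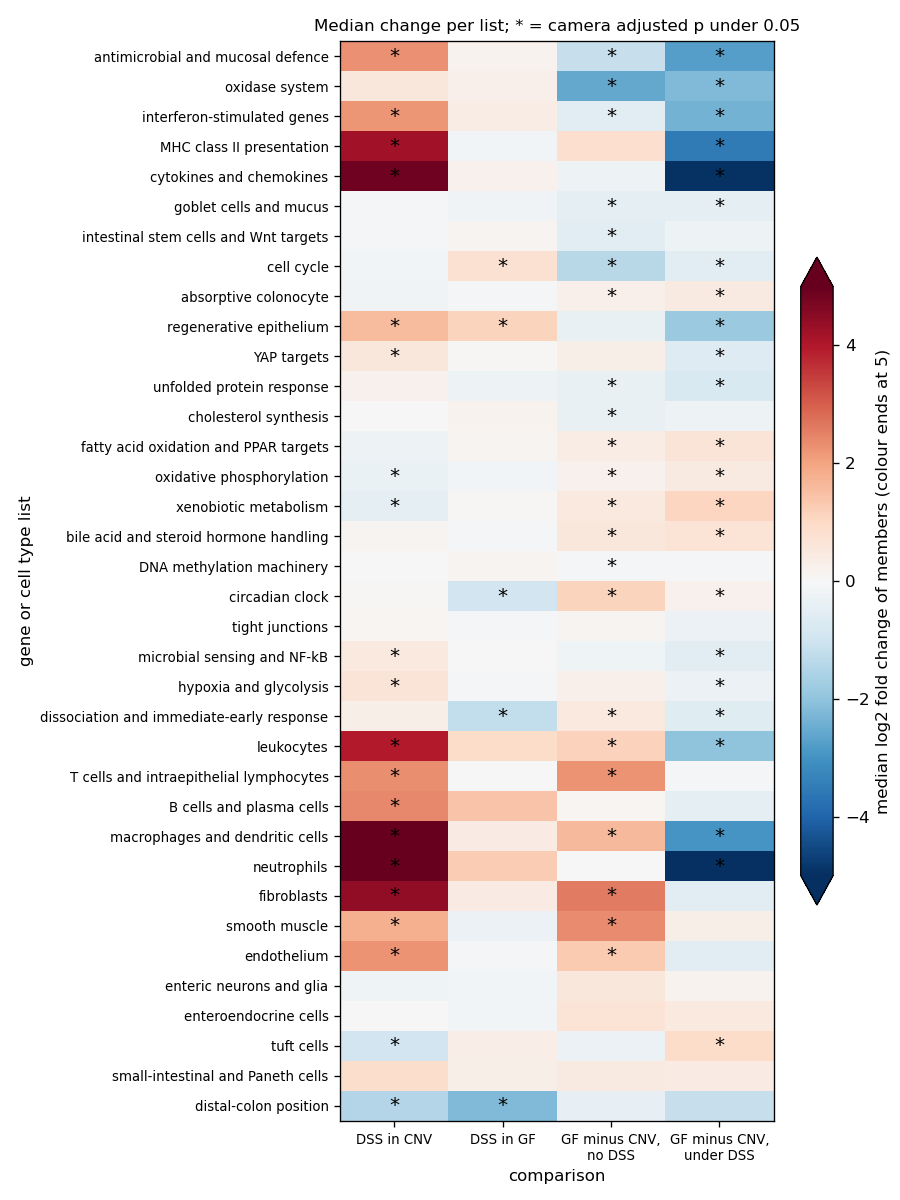
Median log2 fold change of the tested members of 36 lists, 1 line per list, in 4 comparisons, red for higher and blue for lower, with a star where the camera adjusted p was under 0.05. Colours end at 5 on the log2 scale, and 0 of the camera calls hold with an estimated correlation.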

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

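The tests here were planned, but the number of regroupings was raised from 60 to 100 after the first run had been seen. The DSS changes of germ-free and control mice differed in a direct test for 2538 genes. Positive log2 differences were found for Mptx1 (9.91), Mptx2 (9.30), Slc30a10 (7.67), Pla2g4c (5.48), Tppp3 (4.84) and Uhrf1 (1.49). Negative ones were found for Ccl3 (-10.53), Gp49a (-9.57), Lilrb4 (-9.09), Csf3r (-8.50), Fcgr3 (-8.41), Ido1 (-8.40), Nos2 (-5.21), Cd74 (-5.17), Fut2 (-1.69) and Tet3 (-0.65). Ccl3 had 2 counts in CNV, so its fitted value depends on the prior count and is no bound. Pla2g4c and Uhrf1 were already lower in GF than in CNV without DSS, so their positive values can reflect that start.

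Regrouping the libraries cannot show whether chance gives 2538 genes. Of 100 splits drawn from 200, 4 gave as many genes, the real split included, and the highest other gave 5279. That is a share of 4%, and the first run, with 60 splits, held the same 4, a share of 6.67%. The make-up of the splits fixes such counts. A split that mixes GF with GF_DSS shrinks their difference, so the DSS change in CNV itself is counted. Exchanging GF with GF_DSS, which gave the 5279, turns the difference of the DSS changes into their sum. A split that mixes CNV with CNV_DSS puts unlike libraries in 1 group, which raises the spread within groups and lowers the count.

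For each pair of groups the 6 libraries split in only 10 ways, too few for a share under 5%. DSS in CNV gave 5386 genes, against 0 in the highest other split, and DSS in GF gave 1629 against 0. GF against CNV gave 4536 without DSS against 0, and 5564 under DSS against 1. In each of these, 1 split, the real one, gave as many genes. The other splits mix the 2 groups, which raises the spread within groups here too.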

How the results depend on the processing

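The thinning was chosen after the data were seen, and the other alternatives before. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. No list or named gene reversed past the threshold in any alternative run that tested it. Lists were not tested with the DESeq2 Wald test, limma-voom, the CPM filter, fits of only the groups compared or thinning. The direction with more genes turned in 6 of 20 alternative runs for DSS in CNV, 1 of 20 for DSS in GF, and 5 and 3 of 20 for GF against CNV without and under DSS. It turned in 9 of 19 for the difference of DSS changes. The numbers of genes for DSS in CNV and for GF against CNV under DSS stayed within 1.5 times their value in each. Leaving out a library gave 394 (without GF_DSS replicate 5) to 2434 (without GF replicate 3) genes for DSS in GF. For GF against CNV without DSS it gave 3015 (without CNV replicate 4) to 5126 (without CNV_DSS replicate 17). For the difference of DSS changes it gave 1364 (without GF_DSS replicate 5) to 2416 (without CNV replicate 6). The correlation of DSS changes was 0.275 with limma-voom and 0.228 with no filter on low counts. That of germ-free changes was 0.5 when only the groups compared were fitted. The cause of these shifts was not tested. With an estimated correlation camera called 0 lists in place of 94. Fry, which does not compare a list with other genes, called 93, of which 80 were among the 94. At equal depth 841 of 864 results of named genes stayed on their side of the threshold. None that passed in either run changed direction, and changes of direction among the others were not counted. Depth limits GF most, with at most 21880551 counts per library.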

Other observations

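The tests of time of day, of colon position and of 1 strain variant region as the whole cause were chosen after the result was seen. So were the intervals set beside the chromosome, shared-sequence and pan-epithelial values. The camera test of the position genes for the difference of DSS changes was planned, but its use for colon position was chosen afterwards. Camera called 4 lists in no comparison, and their values without DSS follow. Of 26 tight junction genes, 5 rose and 2 fell (4 and 2 adjusted over the list alone, median 0.13). Tight junction genes had a camera adjusted p = 0.563. Of 19 enteroendocrine markers, 6 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.67), among them Gcg (1.37 ± 0.345) and Sst (1.21 ± 0.349). Enteroendocrine markers had a camera adjusted p = 0.0504. Of 8 enteric neuron and glia markers, 2 rose and 0 fell (1 and 0 adjusted over the list alone, median 0.56). Enteric neuron and glia markers had a camera adjusted p = 0.323. Of 11 small-intestinal and Paneth cell markers, 4 rose and 2 fell (4 and 2 adjusted over the list alone, median 0.45), among them Sis (5.82 ± 1.09). Small-intestinal and Paneth cell markers had a camera adjusted p = 0.0922. Of the erythroid list 2 members could be tested, too few for camera. Alas2, an enzyme of heme synthesis, stood at 0.58 ± 0.847, adjusted p = 0.622 with DSS in CNV.

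Of 51 processed pseudogenes tested, 36 rose in GF without DSS and 42 under DSS (medians 1.52 and 1.79), and their share of counts was at least 0.13% in each germ-free library and at most 0.105% in each other library. This is what a difference in how reads were placed or counted in the germ-free libraries would give, and may be its source. Lower depth of GF is argued against, since 100% of the pseudogenes that rose without DSS had positive values under DSS, where the germ-free libraries were the deeper ones. So is 1 strain variant region as the whole cause. At most 11.8% of the 34 pseudogenes that rose in both (upper bound 27.5%) lie on 1 chromosome. Of 221 genes that rose over 4-fold in both, 211 had a known chromosome, and at most 9% of these (upper bound 13.7%) lie on 1. Strain variants for part of the pattern and reads shared between near-identical copies stay open: the largest chromosome ratio of observed to expected was 1.76 (highest upper bound 2.76, limit 2), and genes with over 50% shared sequence exceeded those under 5% by 0.087 (0.023 to 0.155, limit 0.1). An effect of the microbiota itself stays open too, as untested.

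Of 9 clock genes that peak with Dbp, 9 rose in GF against CNV without DSS (median 2.08), and of 5 that peak opposite 4 fell (median -1.57), with Clock at -0.25 ± 0.201 (edgeR adjusted p = 0.364, n = 3). The difference of 3.64 is consistent with another time of day of collection, a hypothesis that the labels do not settle. In GF_DSS against GF the same sets of clock genes moved apart the other way, with medians of -1.31 and 0.54, so the hypothesis bears on the falls of Dbp, Per2 and Nr1d1 there as well. Library scaling or depth is argued against, since the Dbp value for GF against CNV was 7.63 at equal depth. An effect of the microbiota on the clock stays open, as untested.

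With DSS in CNV 23 of 56 xenobiotic genes fell and 6 rose, 10 of 18 tuft cell markers fell and 1 rose, 12 of 12 leukocyte markers rose, and 14 of 15 fibroblast markers rose and 1 fell (camera adjusted p = 0.437, 0.417, 0.396 and 0.22 with an estimated correlation). Of 20 pan-epithelial markers, 6 fell and 3 rose, with a median of 0.046 and values from -0.787 to 0.63. That argues against dilution of epithelial RNA by RNA of other cells as the whole cause. The interval of the median (-0.278 to 0.199, limit -0.3) came from resampling the markers. It leaves out the spread between libraries and lies close to the limit. A different piece of colon cannot be told apart: of 7 genes of distal-colon position 4 fell in CNV_DSS and 3 were not called (median -1.46, adjusted p = 0.455 with an estimated correlation). Their lowest median, -2.21, came with DSS in GF (5 of 7 fell, adjusted p = 0.677 with an estimated correlation), where tuft and xenobiotic medians were 0.32 and 0.06, but the position genes did not differ between these DSS changes past the threshold (camera adjusted p = 0.533). A loss of particular epithelial cells with inflammation stays open, as untested.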
